A study of Mus musculus with 6 samples.

How the data were processed

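Messenger RNA was profiled in pools of 10 fully grown mouse oocytes, 3 libraries from wild-type (WT) females and 3 from females in which Gdf9-cre removes floxed Nat10 in oocytes (Nat10 cKO). Per the labels' protocols, oocytes were collected after an injection of PMSG, the gonadotropin that stimulates follicle growth, and lysed directly. The labels give the collection window as 32 to 48 h in one place and 36 to 48 h in another. Libraries were made by Smart-seq2, in which oligo-dT primes reverse transcription of polyadenylated RNA and the whole cDNA is amplified and fragmented. Each pool also received 0.2 µl of a 1000-fold dilution of ERCC, a synthetic RNA spike-in, for calibration per the series' design text. Whether counting used the strand of a read is not given in the sources used here.

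Per the submitters' processing notes, Trim Galore 0.6.7, STAR 2.7.10a, featureCounts and the mm10 build were used; their settings and the annotation are not given in the sources used here. The deposited table holds 55291 gene symbols and 1 column per library. In the column of WT replicate 1, the deposited values are whole counts of reads per gene. In the other 5 columns, the deposited values are a scaled signal, in which whole reads were multiplied by 1 factor per library. These factors were 1.38 and 0.945 for WT replicates 2 and 3, and 0.920, 0.908 and 0.932 for Nat10 cKO replicates 1, 2 and 3. The formula behind the factors is not stated, and ERCC rows were not analysed here. Dividing each column by its smallest value gave whole reads, within 0.001, for 100% of values above 0. Every gene of a library shares the factor, so it moves all levels of a library together and keeps their order; whether it measures mRNA content is not known.

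The test fixed before the data were examined was edgeR's quasi-likelihood test on raw counts. After 5 of the columns were seen to hold scaled values, the test was changed to limma (trended, robust empirical Bayes). It was run on log2 of CPM, computed from the recovered reads, plus a pseudocount of 1. The recovered reads also allowed the edgeR test, so the change was a choice, and edgeR became an added alternative. Fold changes are therefore on the log2(value + 1) scale, which understates the change of low genes. Genes were kept by filterByExpr on recovered reads with a minimum count of 10, which left 18353 genes. Levels relative to the bulk of oocyte mRNA used TMM factors (TMM scaling). The second scale used the deposited values, divided by 1 constant for all libraries (deposited scaling). It does not divide by the reads of a library, so differences in depth remain unless the factors remove them. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05, and all tests were two-sided. The deposited total per library and the factor alone were compared by an exact permutation test over 20 assignments, where 0.1 is the smallest possible p. All work used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

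Before the data were examined, 17 gene lists were fixed: deadenylation factors, poly(A) and translational control, meiotic cell cycle, oocyte secreted and zona genes, maternal effect genes, ribosome biogenesis, cytoplasmic ribosomal proteins, mitochondrially encoded proteins, nuclear-encoded oxidative phosphorylation, p53 targets, stress response, chromatin regulators, mRNA modification machinery, early zygotic genome activation genes, and markers of granulosa cells, of theca, stroma and endothelium, and of blood and immune cells. Each list was tested against all other genes with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. The named genes were also fixed by rule: Nat10; the 10 largest rises and 10 largest falls among genes past the threshold with at least 10 CPM on average and no overlap between groups, unnamed gene models left out; the 4 members with the smallest p of each list; and, for the marker lists of other cells, the 4 most abundant members. Genes named outside this rule were chosen after their values were seen, and are said to be.

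Gene positions, transcript lengths and GC content came from GENCODE M21 on GRCm38, the same assembly as mm10; 53292 of the 55291 symbols matched. Exons of 17 of the 83 named genes overlap exons of another annotated gene, 15 of them on the opposite strand, among them Cct6a, Mfhas1, Gpat3, Plek, Bop1, Nop14, Dkc1, Suz12 and Sp110; reads of such pairs cannot be told apart without strand. Tcstv1 and Tcstv3 belong to a family of near-identical copies, and how shared reads were counted is not stated, so their values are uncertain.

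The tests were tested on simulated data drawn from the real means, dispersions and library sizes, with 200 genes changed. For TMM scaling, run on 17966 genes, limma recovered 26.9% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 83.3% of those changed 4-fold, and 3.25% of its calls were unchanged genes. DESeq2 on the same simulation made 15.5% of its calls on unchanged genes. For deposited scaling, run on 17670 genes, limma recovered 0% at 1.5-fold, 1.49% at 2-fold and 75.8% at 4-fold. With only 200 genes changed, the Benjamini-Hochberg cutoff is stricter than where many more genes pass. These rates compare the scales and tests and do not give the power in the data. A planted list of genes raised 1.2-fold was called by camera, and 0 of the lists without a shift were. The simulated genes were drawn independently, whereas the real list of cytoplasmic ribosomal proteins had an estimated correlation of 0.239. The simulation therefore does not show how camera performs on lists of correlated genes.

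Alternatives covered other scalings, filters, pseudocounts, tests and thresholds, the replicate number as a block, leaving out mitochondrial genes, and leaving out each library. Replicate pairs within a group differed by 12.6 to 48.7 times the sampling noise (chi-square per degree of freedom), so no library was counted as a duplicate. In these libraries, 3 reads, the limit that a count of 0 allows, correspond to between 0.0405 and 0.0895 CPM. Such limits cover counting error only. The labels do not say that libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical.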

Results

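The transcriptome of fully grown oocytes lacking NAT10 was compared with that of WT oocytes. NAT10 is the enzyme that acetylates cytidine in RNA to N4-acetylcytidine, and the series' title places the question in translational regulation during oocyte meiotic maturation. Each of the 6 libraries held RNA from 10 oocytes. The recovered reads numbered 33.5, 34.1 and 65.5 M in WT replicates 1, 2 and 3, and 74.1, 47.4 and 71.0 M in Nat10 cKO replicates 1, 2 and 3. Between 23044 and 26440 genes were detected per library. In a principal component analysis of log2 values, the first component held 74.3% of the variance and separated the genotypes, with WT libraries between -39.7 and -23.1 and Nat10 cKO libraries between 20.2 and 44.8.

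Nat10 (chromosome 2, 103721256 to 103761270, GRCm38) was examined first as the targeted gene. Its TMM-scaled level was 42.1, 50.1 and 39.4 CPM in the WT libraries and 5.72, 5.97 and 6.32 CPM in the Nat10 cKO libraries. Nat10 fell by 2.67 on the log2 scale (SE 0.129, limma adjusted p = 4.28e-08, n = 3 per group). All 3 Nat10 cKO libraries lay below all 3 WT libraries. The gene-level count includes exons outside the deleted part, which the labels do not name, so the remaining reads do not measure intact transcript.

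**Figure D1:**
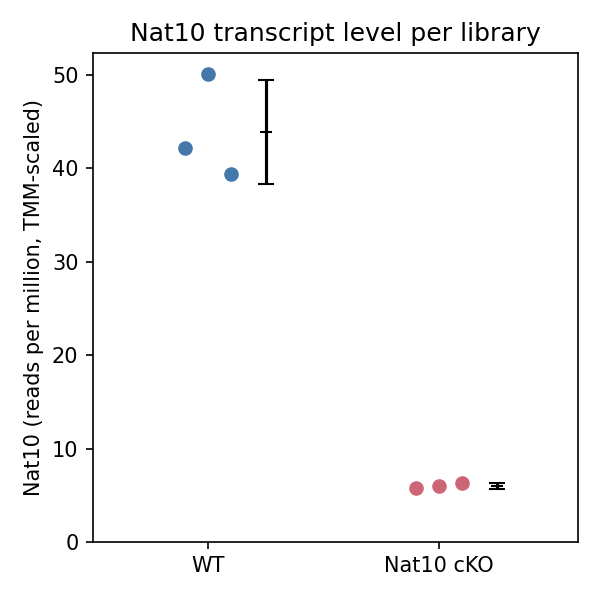
TMM-scaled Nat10 CPM in each library, with points for the 3 libraries of each group and bars for the mean ± SD. WT libraries lie between 39.4 and 50.1 and Nat10 cKO libraries between 5.72 and 6.32.

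Relative to the bulk of oocyte mRNA, gene levels differed widely between the genotypes, mostly by less than 2-fold. Among genes named for their size of change, which average at least 10 CPM, Gpat3, a glycerol-3-phosphate acyltransferase, showed the largest fall, from 19.8 ± 2.65 to 0.725 ± 0.233 CPM (SD, n = 3), 12.0-fold lower on the log2(CPM + 1) scale. Cnpy4 fell from 318 ± 23.2 to 45.4 ± 1.98 CPM and Tceal8 from 66.4 ± 19.6 to 7.06 ± 0.874 CPM. The pleckstrin gene Plek, the chondroitin sulfotransferase gene Chst11, the pseudokinase gene Trib2 and the chemokine receptor gene Cxcr3 fell as well, with log2 changes of -2.42, -2.33, -2.23 and -2.05. The largest rise among them was that of Pls3, which encodes an actin-bundling protein and rose from 4.19 ± 0.167 to 25.2 ± 7.58 CPM, a log2 change of 2.29. Tfrc, the transferrin receptor gene, rose from 13.7 ± 1.01 to 63.9 ± 20.6 CPM, and Mfhas1 from 8.23 ± 2.02 to 38.4 ± 2.65 CPM. Uqcrc1, a core subunit of respiratory complex III, rose by a log2 change of 2.11 (SE 0.224). Piwil2, of the piRNA pathway, rose by 1.93 and Gcsh, of the glycine cleavage system, by 1.91. The rises of Cct6a, G2e3, Maged1 and Wdr45b were 2.18, 2.10, 2.08 and 1.81. Adjusted p-values of the 10 largest rises and 10 largest falls, Nat10 included, ranged up to 0.00162.

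In all, 6422 of 18353 tested genes passed the limma threshold, 3190 higher and 3232 lower in Nat10 cKO oocytes. Of these, 823 changed at least 2-fold, 459 higher and 364 lower. The median size of a called change was 0.56 on the log2 scale for rises and 0.55 for falls. The groups did not overlap for 8873 genes, 48.3% of those tested, where chance gives 10%. Without WT replicate 3, 2108 genes were higher and 2201 lower. edgeR on the recovered reads called 6202 genes, of which 6119 were also called by limma in the same direction. Without the pseudocount of 1, more of the edgeR calls reached 2-fold: 2081 genes, 1076 higher and 1005 lower. The limma count of 823 therefore depends on the pseudocount.

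**Figure D2:**
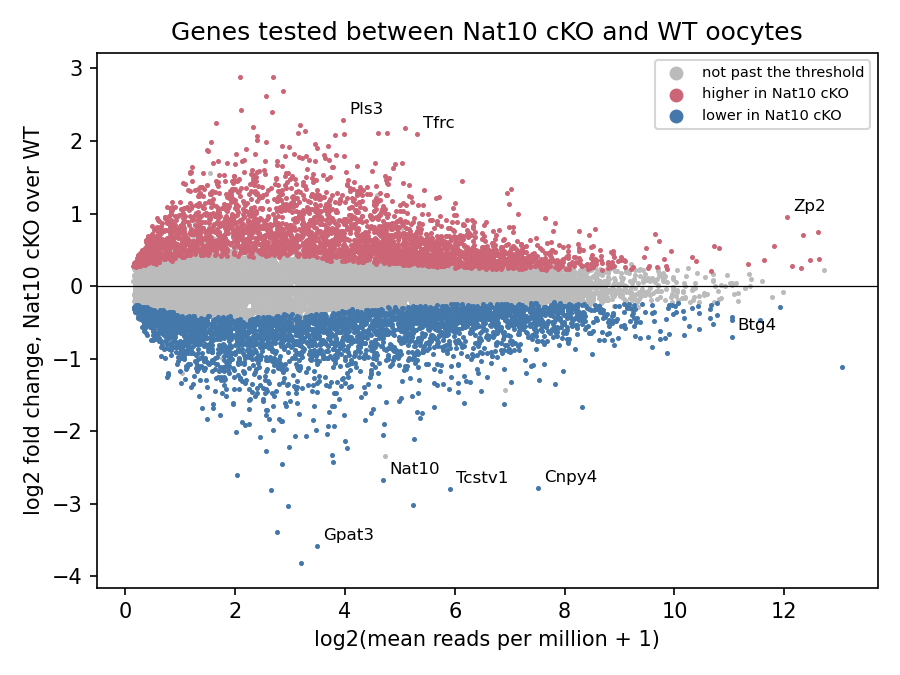
Log2 fold change of Nat10 cKO over WT against log2 of the mean CPM plus 1, one point per tested gene, coloured by direction where adjusted p is under 0.05. The 3190 higher and 3232 lower genes are spread over the whole range of expression, with Gpat3 and Nat10 among the lowest points.

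**Figure D3:**
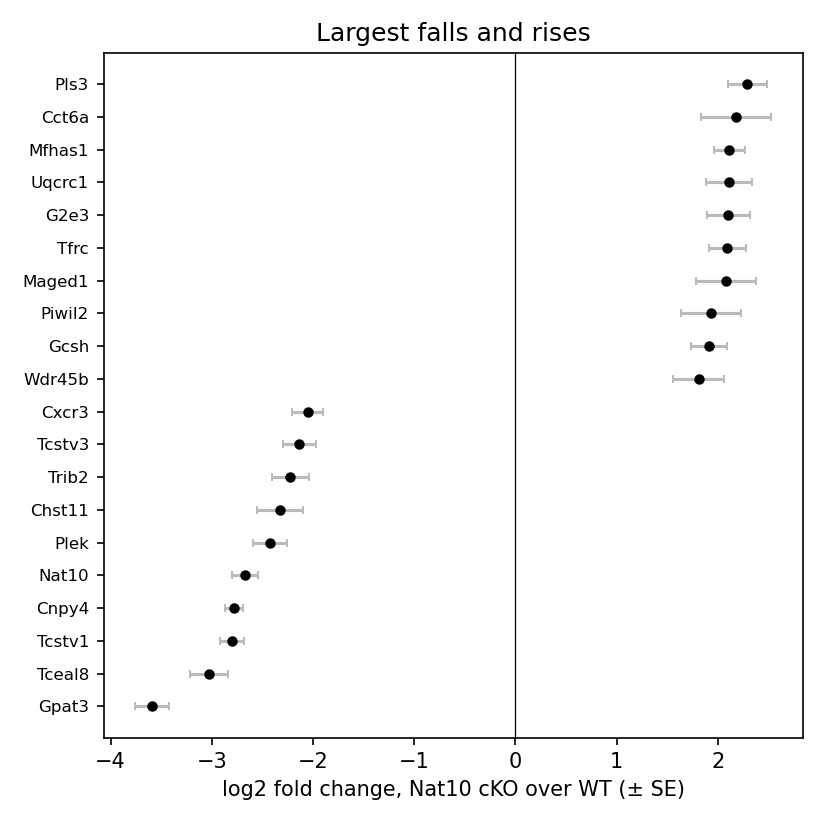
Log2 fold changes of the genes with the largest falls and rises under the naming rule, with bars for the SE. Gpat3 lies at -3.59 and Pls3 at 2.29.

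Under TMM scaling, oocyte growth and maternal effect genes moved in both directions. Zp2 and Zp3, which encode zona pellucida proteins, rose from 2885 ± 121 to 5629 ± 949 and from 2922 ± 195 to 4286 ± 432 CPM. Nobox, an oocyte transcription factor gene, rose by 0.72 on the log2 scale (SE 0.102), whereas Fgf8 fell by 0.71 (SE 0.115). Of 30 tested genes of the secreted, zona and transcription factor list, 11 rose and 11 fell, with the same numbers adjusted over the list alone; 2 rose and 0 fell as deposited, and 3 rose and 12 fell with the deposited factors applied to per-read shares. Among 31 maternal effect genes, 8 rose and 8 fell, again the same adjusted over the list alone, against 2 and 0 as deposited and 3 and 7 on per-read shares. The maternal effect falls were 5 without WT replicate 1 or Nat10 cKO replicate 1 and 4 without Nat10 cKO replicate 2, and without WT replicate 3 there were 5 rises and 5 falls. Padi6, Nlrp5 and Nlrp14 rose by 0.70, 0.56 and 0.74, and Bnc1 fell by 0.73. Neither list stood apart from other genes in camera (adjusted p = 0.948 and 0.689; 0.935 and 0.870 with an estimated correlation). Markers of granulosa cells, which surround the oocyte, summed to 450 ± 27.4 CPM in WT and 432 ± 17.8 CPM in Nat10 cKO libraries. Serpine2 alone made up 322 CPM of the WT sum and 298 CPM of the Nat10 cKO sum. The sums therefore mostly reflect this 1 gene and say little about the list as a whole.

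Deadenylation and translational control genes were examined because maternal mRNAs are stored and later removed through their poly(A) tails. Btg4, the adaptor that brings the CCR4-NOT deadenylase to maternal mRNAs, fell from 2609 ± 318 to 1601 ± 89.6 CPM (log2 change -0.70, SE 0.094, adjusted p = 0.000188). Noct, Pan3 and Cnot6l also fell, with log2 changes of -0.76, -0.66 and -0.48. Of 19 deadenylation factors, 6 fell and 3 rose, the same adjusted over the list alone, against 0 and 0 as deposited and 6 and 0 on per-read shares. The rises were 1 without WT replicate 3 and 0 without Nat10 cKO replicate 1 or 2. In the list for poly(A) and translational control, 14 of 41 genes fell and 7 rose, or 16 and 8 adjusted over the list alone, against 0 and 2 as deposited and 11 and 3 on per-read shares. The falls were 9 without WT replicate 3 and 8 without Nat10 cKO replicate 1, and 9 fell and 4 rose without Nat10 cKO replicate 2. Zar1 and Pabpn1l fell, with log2 changes of -0.66 and -0.75, while Pabpc1, a cytoplasmic poly(A)-binding protein gene, rose by 1.24 and Edc3 by 1.11. Of 53 meiotic genes, 12 fell and 10 rose under TMM scaling, or 13 and 10 adjusted over the list alone, against 0 and 1 as deposited and 13 and 1 on per-read shares. The meiotic rises were 4, 6 and 5 without WT replicate 3, Nat10 cKO replicate 1 and Nat10 cKO replicate 2. Bub1b, Aurkc and Fbxo43, which act in spindle checkpoint and meiotic control, fell, with log2 changes of -0.63, -0.54 and -0.49. Camera placed none of these 3 lists apart from other genes (adjusted p = 0.252, 0.689 and 0.899; 0.870, 0.870 and 0.935 with an estimated correlation).

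Under TMM scaling, genes of ribosome production and respiration rose more often than they fell, which for ribosomal proteins turned to 1 rise and 4 falls on per-read shares. Of 64 ribosome biogenesis and nucleolar genes, 19 rose and 5 fell, the same adjusted over the list alone, against 7 and 0 as deposited and 6 and 4 on per-read shares; 3 fell without WT replicate 3. Polr1c, Bop1 and Nop14 rose by 1.01, 1.06 and 0.69, and Dkc1, a pseudouridine synthase gene, fell by 0.59. Among 62 nuclear-encoded oxidative phosphorylation genes, 16 rose and 3 fell, the same adjusted over the list alone, with Cyc1, Atp5d and Atp5g3 rising by 1.25, 0.88 and 0.70. That list had 3 rises and 0 falls as deposited and 3 and 2 on per-read shares, and its falls were 5 without WT replicate 2 and 1 without WT replicate 1 or 3 or Nat10 cKO replicate 1 or 2. Of 79 cytoplasmic ribosomal protein genes, 16 rose and 4 fell, or 13 and 3 adjusted over the list alone; Rps3, Rpsa and Rpl29 rose by 0.55, 0.55 and 0.53 and Rpl17 fell by 0.51. As deposited, 1 ribosomal protein gene rose and 0 fell. Rises were 10 without WT replicate 1 or 3 or Nat10 cKO replicate 1 or 2, with 2, 1, 5 and 1 falls, and without WT replicate 2 there were 16 rises and 9 falls. The median of the ribosomal protein list was -0.0026 and its mean 0.039, so they differ in sign. Only mt-Co1 passed among 11 mitochondrially encoded genes (0.40, adjusted p = 0.0497), 0 passed adjusted over the list alone, and edgeR gave mt-Co1 an adjusted p of 0.0574. As deposited and on per-read shares 0 mitochondrial genes passed, and 2 passed without WT replicate 3 and 0 without WT replicate 1 or 2 or Nat10 cKO replicate 1 or 2. None of these lists passed camera, with adjusted p = 0.120 for ribosome biogenesis, 0.192 for oxidative phosphorylation, 0.689 for ribosomal proteins and 0.689 for mitochondrial genes. With an estimated correlation, the adjusted p-values were 0.870, 0.870, 0.935 and 0.935. Ribosome biogenesis passed when WT replicate 2 (adjusted p = 0.0310) or Nat10 cKO replicate 2 (adjusted p = 0.0435) was left out.

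Under TMM scaling, stress response genes rose more often than they fell, which turned to 2 rises and 4 falls on per-read shares. Xbp1, a transcription factor of the unfolded protein response, rose from 0.977 ± 0.448 to 9.81 ± 4.34 CPM (log2 change 2.40) and Hspa5, which encodes a chaperone of the endoplasmic reticulum, rose by 0.57, while the heat shock genes Hspa1b and Hsp90aa1 fell, with log2 changes of -1.39 and -0.55. Of 42 genes in that list, 14 rose and 4 fell, or 15 and 4 adjusted over the list alone, against 3 and 1 as deposited. The rises were 9 without WT replicate 1 and 7 without WT replicate 3. Camera gave an adjusted p = 0.192, and 0.870 with an estimated correlation; without WT replicate 2 the list passed (adjusted p = 0.0437). Among 28 p53 and apoptosis genes, 7 rose and 4 fell, the same adjusted over the list alone, against 3 and 0 as deposited and 2 and 2 on per-read shares; 2 fell without WT replicate 1 or 3 or Nat10 cKO replicate 1. Ccng1 rose from 8.08 ± 0.714 to 19.9 ± 1.11 CPM, Trp63 and Trp53 rose by 0.59 and 0.51 on the log2 scale and Apaf1 fell by 0.81 (camera adjusted p = 0.252; 0.870 with an estimated correlation).

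Chromatin regulators fell more often than they rose under TMM scaling, with 16 falls and 9 rises, and on per-read shares, with 13 and 4, but had 0 falls and 5 rises as deposited. Suz12, a Polycomb subunit gene, and Tet3, a methylcytosine dioxygenase gene, fell, with log2 changes of -1.07 and -0.71, while Kdm5a and Ehmt2 rose by 1.55 and 1.45. The numbers for the 63 tested chromatin regulators were the same adjusted over the list alone, and 9 fell without Nat10 cKO replicate 2 (camera adjusted p = 0.899; 0.935 with an estimated correlation). Of 32 mRNA modification genes, 8 fell and 8 rose, or 8 and 9 adjusted over the list alone, against 0 and 2 as deposited and 5 and 3 on per-read shares. The falls in this list were 5 without WT replicate 1; 3 fell and 5 rose without Nat10 cKO replicate 1, and 3 fell and 3 rose without WT replicate 3 or Nat10 cKO replicate 2. Mettl14, of the m6A methyltransferase, fell by 0.51 and Pus1 and Trmt61a rose by 0.87 and 0.80 (camera adjusted p = 0.917; 0.935 with an estimated correlation). Of 12 tested genes of early zygotic genome activation, 4 fell and 2 rose, the same adjusted over the list alone and on per-read shares. The rises rested on single libraries, at 6 without Nat10 cKO replicate 3, 0 without WT replicate 3 and 1 without Nat10 cKO replicate 1 or 2. Tcstv1 fell from 104 ± 5.99 to 14.2 ± 2.21 CPM and Tcstv3 from 25.1 ± 4.66 to 4.91 ± 0.826 CPM, and Tmem92 and Sp110 fell, with log2 changes of -1.03 and -0.48 (camera adjusted p = 0.252; 0.870 with an estimated correlation).

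Across the 17 lists, 0 passed camera, against 3 at an unadjusted p under 0.05; with an estimated correlation 0 passed, and 0 at an unadjusted p under 0.05. Median and mean also differed in sign for the secreted and zona list (-0.037 and 0.027, tested upward), the mRNA modification list (-0.021 and 0.060, tested upward) and the blood list (0.034 and -0.0027, tested downward), and the chromatin list had a median of 0.020 and was tested downward. fry, which asks whether a list moves on balance one way without comparing it with other genes, called 3 lists: ribosome biogenesis and p53 targets upward and early zygotic genes downward. Its test for change in either direction called 16, all but the mitochondrially encoded list. With 6422 of 18353 tested genes called, most lists could be expected to pass it, so these calls do not single out any list.

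**Figure D4:**
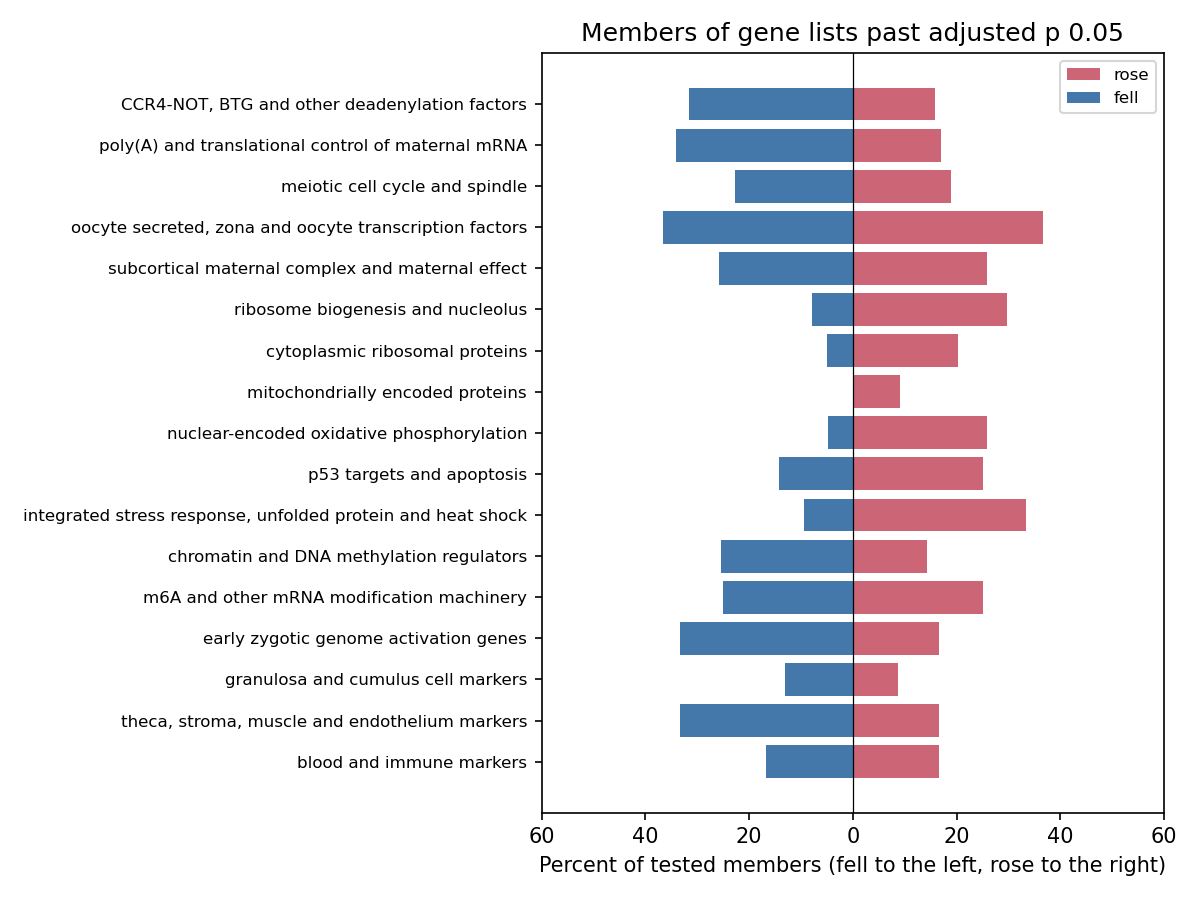
Percent of tested members of each gene list that fell (left) or rose (right) at an adjusted p under 0.05. Ribosome biogenesis had 19 rises against 5 falls, whereas the secreted and zona list had 11 of each, both under TMM scaling; as deposited they had 7 against 0 and 2 against 0, and on per-read shares 6 against 4 and 3 against 12.

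Markers of blood and immune cells summed to 54.6 ± 2.30 CPM in WT and 43.9 ± 2.08 CPM in Nat10 cKO libraries, with all 3 Nat10 cKO libraries below all 3 WT libraries. C1qb alone made up 44.0 CPM of the WT sum and 32.1 CPM of the Nat10 cKO sum. The blood sums therefore mostly reflect this 1 gene and say little about the list as a whole. Of 6 tested blood genes, 1 rose and 1 fell, the same adjusted over the list alone, against 0 and 0 as deposited and 0 and 1 on per-read shares. The fall was in C1qb, from 44.0 ± 2.87 to 32.1 ± 0.521 CPM; H2-Aa, Cd68 and Csf1r had log2 changes of 0.09, 0.21 and -0.28. The rise was lost without WT replicate 1, 2 or 3 or Nat10 cKO replicate 2, where 0 rose. Of 23 granulosa markers, 2 rose and 3 fell, or 2 and 2 adjusted over the list alone, against 3 and 0 as deposited and 2 and 3 on per-read shares. Without WT replicate 1 or Nat10 cKO replicate 1 there were 1 and 1, without WT replicate 2 there were 1 and 4, without WT replicate 3 there were 1 and 2, and without Nat10 cKO replicate 2 there were 5 rises and 1 fall. Their most abundant members, Serpine2, Cyp19a1, Nr5a2 and Gata4, had log2 changes of -0.11, -0.32, 0.23 and 0.17, of which only Cyp19a1 passed (adjusted p = 0.0488). Its call was lost with median-of-ratios factors (adjusted p = 0.0542), library sizes only (0.0628), no filter (0.135) or the replicate number as a block (0.0534), and without any 1 library other than WT replicate 2. Of 12 theca, stroma and endothelium markers, 2 rose and 4 fell, the same adjusted over the list alone, with Pecam1 rising by 0.51, Myh11 falling by 0.63, and Cnn1 and Tek at -0.11 and -0.08. The call of Myh11 was lost without WT replicate 2 or Nat10 cKO replicate 2. The list summed to 152 ± 4.81 CPM in WT and 150 ± 9.96 in Nat10 cKO libraries. These markers had 0 rises and 1 fall as deposited and 0 and 4 on per-read shares. They had 1 and 3 without WT replicate 1, 2 and 1 without WT replicate 2, 1 and 2 without WT replicate 3 or Nat10 cKO replicate 1, and 1 and 1 without Nat10 cKO replicate 2. Camera gave the granulosa, theca and blood lists adjusted p-values of 0.899, 0.689 and 0.917, and 0.935, 0.870 and 0.935 with an estimated correlation.

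The deposited values were compared as a second scale, since the spike-in was added for calibration. The largest changes held on this scale: Gpat3, Nat10 and Cnpy4 fell, with log2 changes of -3.31, -2.33 and -2.42, while Pls3 rose by 2.59, Tfrc by 2.43 and Xbp1 by 2.58. Zp2 and Cyc1 also rose, by 1.31 and 1.59 (limma adjusted p = 0.0131 and 0.00281). Btg4, Zar1, Bub1b and Tet3 did not pass, with log2 changes of -0.34, -0.30, -0.27 and -0.35 (adjusted p = 0.654, 0.704, 0.738 and 0.650). Nobox, Padi6, Zp3 and Nlrp5 did not pass either, although their log2 changes of 1.08, 1.06, 0.91 and 0.92 were larger than under TMM scaling (adjusted p = 0.0648, 0.0631, 0.135 and 0.136). Of the 82 named genes other than Nat10, 36 lost their call, 14 higher genes with a larger change than under TMM scaling and 22 lower genes with a smaller one, and Cyp19a1 turned from -0.32 to 0.031. With the factors on per-read shares, 13 of the 82 lost their call, 12 higher genes, Zp3 and Nlrp5 among them, with a smaller change than under TMM scaling, and Cyp19a1. As deposited, among deadenylation factors 0 rose and 0 fell, among ribosome biogenesis genes 7 rose and 0 fell, and among early zygotic genes 3 rose and 2 fell.

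On the deposited scale, 1462 genes passed, 1207 higher and 255 lower in Nat10 cKO oocytes, or 82.6% higher against 49.7% under TMM scaling. The median log2 change of all tested genes was 0.24 on this scale. The deposited totals averaged 47.5 ± 14.2 M in WT and 59.2 ± 14.0 M in Nat10 cKO libraries (SD, n = 3), a log2 difference of 0.33 that was within the spread between libraries (exact permutation p = 0.4, smallest possible 0.1). The factors alone pointed the other way, with a log2 difference of -0.25 and all 3 Nat10 cKO factors below all 3 WT factors (exact permutation p = 0.1, the smallest possible). The Nat10 cKO factors lay close together, at 0.920, 0.908 and 0.932. The deposited totals of these libraries, 68.2, 43.0 and 66.2 M, therefore followed their reads of 74.1, 47.4 and 71.0 M. Reads averaged 64.2 M in Nat10 cKO and 44.4 M in WT libraries. The shift towards higher genes on the deposited scale thus cannot be told apart from depth. Whether the deposited totals or the factors alone measure mRNA per oocyte is open, because the formula of the factors is not stated. Applied instead to per-read shares, an alternative chosen after seeing the data, the factors gave 4053 genes, 1024 higher and 3029 lower, with a median of -0.15. The deposited-scale count was 733 without WT replicate 2, 422 without Nat10 cKO replicate 1 and 687 without Nat10 cKO replicate 3. Its balance rested in part on WT replicate 1, without which 676 genes were higher and 435 lower. Higher and lower genes numbered 604 and 129 without WT replicate 2, 1399 and 130 without WT replicate 3, and 339 and 83, 1625 and 121, and 561 and 126 without Nat10 cKO replicates 1, 2 and 3.

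**Figure D5:**
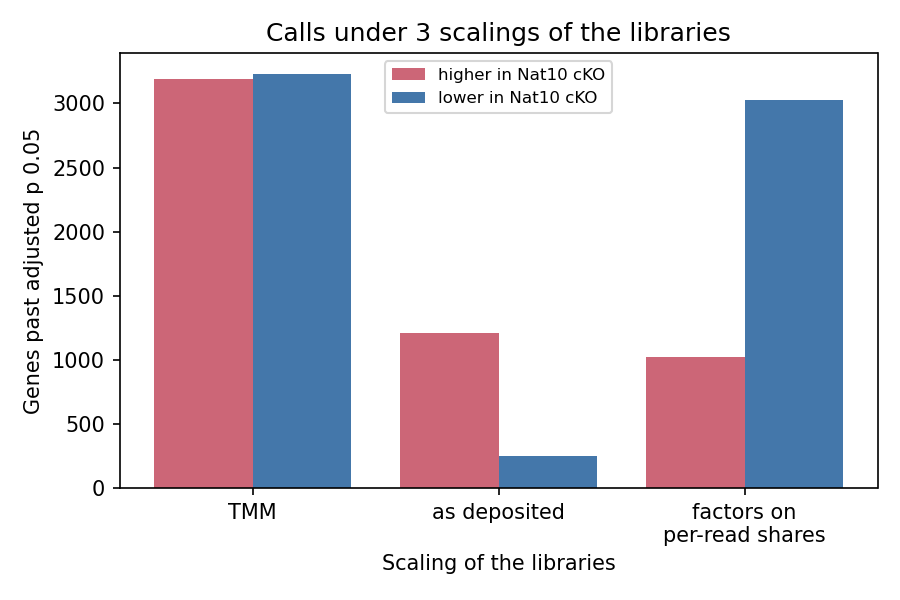
Number of genes past an adjusted p of 0.05 that were higher or lower in Nat10 cKO oocytes under each scaling of the libraries. The balance shifts from 3190 higher and 3232 lower under TMM scaling to 1207 and 255 as deposited and 1024 and 3029 with factors on per-read shares.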

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

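Settings beyond the fixed alternatives (edgeR, other pseudocounts, the deposited scale for the TMM results, factors on per-read shares, trend removal and thinning) were chosen after seeing the data. Nat10 fell in every setting tried, with log2 changes from -2.15 to -2.87. The TMM count of 6422 genes became 1462 on the deposited scale and 4053 with factors on per-read shares, 823 with a 2-fold minimum and 3730 at an adjusted p under 0.01; in the other settings it stayed within 1.5 times, and leaving out 1 library gave 4309 to 6682. The deposited-scale count of 1462 became 474 with at least 5 CPM in 3 libraries, 943 with a 2-fold minimum and 4053 with factors on per-read shares, and leaving out 1 library gave 422 (without Nat10 cKO replicate 1) to 1746, with 733 without WT replicate 2 and 687 without Nat10 cKO replicate 3; the cause was not tested, beyond fewer genes or libraries entering.

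The number of lists past the set test, 0, became 3 with no filter (ribosome biogenesis, oxidative phosphorylation, stress response). It was 1 with the stricter filter (early zygotic genes, 4 tested) and 3 with fry. Leaving out 1 library gave 0 to 2, with 2 without WT replicate 2 and 1 without Nat10 cKO replicate 2. The cause was not tested. Splits that mix the genotypes had up to 6 lists past camera at the preset correlation. A camera pass in 1 setting therefore does not show an effect of genotype. The log2 difference in deposited totals, 0.33, turned to -0.25 when the factor alone was compared (exact permutation p = 0.1, the smallest possible, with the groups fully apart), because the difference in reads then drops out, and ranged from 0.10 (without WT replicate 1) to 0.55 (without Nat10 cKO replicate 2) when 1 library was left out, with 0.54 without WT replicate 3 and 0.21 without Nat10 cKO replicate 1. Cyp19a1 turned to 0.031 on the deposited scale, and of the 82 named genes 36 lost their call there and 13 on per-read shares. The alternatives that need counts of single ERCC species were not run.

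Replicate numbers did not pair the libraries: same-number deviations correlated at 0.079, 0.075 and -0.12, and not every library correlated best with its own number. With the replicate number as a block, the TMM count was 6234, the deposited-scale count 681, the lists past the test 0 and Nat10 -2.67. A simulated 2-fold change was recovered in 1.49% of genes on the deposited scale, against 68.7% under TMM scaling. Without mitochondrial genes their list has no test.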

Other observations

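The tests on the order of libraries (all but depth), on ribosomal RNA and on the polyadenylation element were chosen only after the result was seen. Long non-coding genes fell more often than they rose: of 1227 tested lincRNA genes, 327 fell and 67 rose, with a median log2 change of -0.14 (camera adjusted p = 0.000198 over 6 gene types, 0.360 with an estimated correlation). Among 621 antisense genes, whose reads cannot be told from those of their partners without strand, 115 fell and 41 rose (adjusted p = 0.0311; 0.360 with an estimated correlation), and among 13956 protein-coding genes 2435 fell and 2918 rose (adjusted p = 0.00605; 0.0397 with an estimated correlation). On the deposited scale 43 lincRNA and 14 antisense genes fell and 35 and 22 rose, so the antisense balance turned, and 159 protein-coding genes fell and 1083 rose; with the factors on per-read shares 331 and 118 fell and 26 and 17 rose, and protein-coding genes turned to 2193 falls and 928 rises. Of 26 tested replication-dependent histone genes, 5 rose and 5 fell, and H4c4, chosen after its values were seen, rose from 0.353 ± 0.172 to 6.31 ± 0.903 CPM.

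The breadth of the change, 6422 genes, was weighed against 3 explanations. Of the 10 splits of the 6 libraries, 1 gave as many genes, the real one, and the highest other gave 0; 10 splits are too few for a share under 0.05. The same holds on the deposited scale, where 1 split gave 1462 genes and the highest other gave 1. For the lists, the real split gave 0 past the test, so that 10 of 10 had to give as many. The highest other gave 6, with WT replicates 1 and 3 beside Nat10 cKO replicate 1, and 0 genes called under TMM scaling. Camera at the preset correlation thus called lists in splits that do not follow genotype. Its passes alone therefore do not show an effect of genotype. Every other split puts libraries of both genotypes on each side. Whatever separates the real groups then adds to the spread within groups, and few gene calls were bound to follow. The low gene counts of the other splits therefore do not bear on the cause. Removing each library's trend with GC content and transcript length gave 6767 calls against 6315 before on the same genes, and thinning all libraries to the smallest gave 6212, which argues against these trends and against depth as the whole cause. The genotype and any difference between animals or collection days that ran with it cannot be told apart here, and the latter was not tested.

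Within groups, libraries appeared ordered along the genotype contrast. Across 18353 genes, which are not independent replicates, the difference of Nat10 cKO replicate 1 from the WT mean correlated with the difference between Nat10 cKO replicates 2 and 3, which share no library (Spearman's rho 0.51); for the difference of the Nat10 cKO mean from WT replicate 3 against that between WT replicates 2 and 1 it was 0.296. With GC and length trends removed rho was 0.521 and with thinned reads 0.495, against both as the whole cause in Nat10 cKO libraries, while in WT libraries, at 0.259 and 0.293, the tests decide nothing, since rho lay below their bound before any correction. WT RNA mixed into Nat10 cKO replicate 3, at the share of 15.8% that 363 fallen genes imply, would have lifted Nat10 by 5.99 CPM above replicate 2; the observed lift was 0.353, or 0.0589 of that. A hypothesis left open is that pools differed in oocyte maturity and that the genotype contrast may run along the same axis, which was not tested.

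Ribosomal RNA reads were lower in Nat10 cKO libraries, a feature chosen after its values were seen. The annotated rRNA gene CT010467.1 (chromosome 17, 39846353 to 39848827), whose exons overlap Gm42418 on the opposite strand so that reads of the pair cannot be told apart, fell from 11601 ± 1036 to 5357 ± 566 CPM (log2 change -1.12), and mt-Rnr1 and mt-Rnr2 fell by 0.52 and 0.44. Dilution by a larger mRNA pool stays open. On the deposited scale the change of CT010467.1 was -0.76 (limma adjusted p = 0.239). Those of mt-Rnr1 and mt-Rnr2 were -0.16 and -0.082 (limma adjusted p = 0.853 and 0.926), so their falls were not seen on that scale. The deposited scale, which keeps differences in depth, raised the median of all tested genes to 0.24. With the factors on per-read shares that median was -0.15. The factors alone, with a log2 difference of -0.25, would mean a smaller mRNA pool in Nat10 cKO oocytes, which goes against dilution. Which use of the factors measures mRNA content is not known. Lower capture of RNA without a poly(A) tail was examined in the 26 histone genes, of which 5 rose and 5 fell. Their median was -0.070 (SE 0.115), and the lowest, H2ac6, was at -0.66. A fall as large as that of CT010467.1 was thus not shared by them. By the bounds written for the median, however, the test was undecided. Whether histone reads in these libraries come from RNA without a tail is also not known. Lower capture therefore stays open. A lower rRNA content of the oocytes may be the source too, since NAT10 is known to act on 18S rRNA, and was not tested.

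A further hypothesis was that transcripts carrying a cytoplasmic polyadenylation element moved together. Among 12901 genes with a 3' UTR of at least 100 nt, the 2447 with the element in its last 100 nt had a median log2 change of -0.029, against 0.049 for the other 10454. With GC and length trends removed, the medians differed by -0.057. Adjusted over the 3 fits, camera gave an adjusted p = 0.110, 0.0910 with an estimated correlation and 0.313 with that and the trends removed. Unadjusted, 1 of the 3, the one with an estimated correlation and no trend removed, lay under 0.05; the adjustment and the use of the difference in medians as the deciding value were chosen after that was seen, so the hypothesis stays undecided.

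The scaling factors of the deposited table stand in ratios of small whole numbers. Their inverses are proportional to 69, 50 and 73 in WT replicates 1, 2 and 3 and to 75, 76 and 74 in Nat10 cKO replicates 1, 2 and 3, and 69 is the smallest number for WT replicate 1 that makes all 6 whole within 0.001. Reads differed more, from 33.5 to 74.1 M, and what these numbers count is not stated in the sources used here, so neither use of the factors is known to measure mRNA content.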
